A study of Xenopus tropicalis with 4 samples.

How the data were processed

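WTTS-seq (whole transcriptome termini site sequencing) reads the 3' ends of polyadenylated RNA, so that each read is taken to report a polyadenylation site. Priming on A-rich stretches within RNA could also give reads, and sites were not checked for it. Libraries were made from total RNA of whole-body homogenates of 4 individual adult Xenopus tropicalis frogs, 2 females and 2 males, per the labels. RNA was extracted with Trizol, fragmented, enriched for poly(A) RNA, copied into first-strand cDNA, size-selected and amplified by PCR, per the labels' protocols. Reads carry no molecular identifiers as far as the labels say, so intervals and floors below cover counting error only. Bowtie2 2.2.3 is named in the submitters' processing notes. The genome build, the way reads were grouped into sites and any filter on sites are not given in the sources used here.

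The authors deposited 1 table of raw read counts per polyadenylation site, with a strand, a position, a start and an end, a gene, a transcript and a class code for each site, per the file headers. It lists 66426 sites, of which 7380 have no gene, and names 15410 genes. A single line without a site held the column totals and was left out. The same deposited table gives p-values of the authors' own test of the sexes (raw, FDR and Bonferroni adjusted) and a signed fold change, with no tool named. Its sign is positive where females are higher, as judged from the counts. Read totals were 2380500 and 1778737 in females 1 and 2, and 2779715 and 1531471 in males 1 and 2. Positions are printed as the table gives them, and whether they count from 0 or 1 is not given. Chromosome numbers were assigned from where the sites' gene symbols lie in a RefSeq gene table (assembly UCB_Xtro_10.0), which was used for names and chromosome numbers and for no position. Of 15262 symbols, 13848 were in that table and 608 more matched by an identifier or a synonym.

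The class codes were read as in Cuffcompare, a scheme the file does not name. A site's class code places it inside an exon, overlapping an exon, across an exon and an intron, downstream of the gene, within an intron or on the strand opposite to an exon. Each gene's strand was taken from its exonic and downstream sites, or from exonic sites on the opposite strand where it had no others, and 982 sites lay in genes of unknown strand. Gene sums and the site use test left out the 2709 sites on the opposite strand, which held 3.84% and 2.87% of reads in the females and 0.89% and 0.51% in the males. That was decided after the class codes were seen, and sums with these sites were tried as an alternative. Sites without a gene held 3.98% and 14.37% of reads in the females and 13.12% and 9.43% in the males, and entered the site test only. Genes that share a symbol were kept apart by their identifier. Reads shared between near-identical copies cannot be assigned with certainty.

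Sites and gene sums were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest on sex, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute fitted log2 fold change divided by the square root of the F statistic. CPM values are read counts scaled to the effective library size. Log2 fold changes are male over female, so a negative value means higher in females. Where a sex had 0 reads in both libraries, the fold is a lower bound against 3 reads over that sex's summed effective library, written "at least". With 1 to 3 reads in the lower sex, a ratio with its 95% Clopper-Pearson counting interval is given. Site use was tested with diffSpliceDGE (gene-level F test) in genes with at least 2 tested sites, and a site's use is its share of its gene's reads at tested sites. The site index of a gene is the read-weighted rank of its sites along the strand, from 0 (most upstream) to 1 (most downstream). With 2 libraries against 2, the smallest two-sided p of an exact permutation test is 0.333.

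The 19 gene lists were fixed before the data were examined, as were the tests, 70 alternatives and the rule for named genes, while 8 alternatives were added after. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, on log2 CPM with a prior count of 2, with an estimated correlation and with fry as alternatives. At the preset, camera takes its degrees of freedom from the number of genes, so its p does not measure the spread between frogs. With an estimated correlation the degrees of freedom come from the frogs. Named genes have a symbol and pass the gene test with no overlap of the sexes. In each direction they are the 6 of highest mean CPM and the 6 of largest fold change at a mean CPM of at least 10. For site use the 10 genes of smallest p at a mean CPM of at least 10 are named. Up to 4 members of smallest adjusted p are named per list, and a fixed set of genes was to be reported whatever the result. Of these, vtgb1, dmrt1, amh, foxl2 and cyp19a1 are not analysed here. Alternatives covered the normalization, the low-count filter, the test (DESeq2 1.42.0, limma voom), the sites used, the replicate number as a block, and each library left out in turn.

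The steps were tested on simulated counts drawn from the real means and library sizes. Of 9685 simulated genes tested, 0, 6.52, 46.9 and 79.2% of those changed were called at true log2 folds of 1, 2, 3 and 4, with 5 calls of unchanged genes. Of 14930 sites these shares were 0, 0, 6.52 and 12.5%, with 0 calls of unchanged sites. For site use, over 2907 genes, they were 0, 2.5, 2.27 and 24.4%, with 0 calls of unchanged genes. The simulation changed 191 of the tested genes, 185 of the sites and a site in each of 172 genes, up and down alike. Far more sites and genes were called in the data, so these shares and false calls do not describe the tests of the data. A list of 30 genes raised by 1 on the log2 scale had a camera p of 2.53e-07 and an unchanged list one of 0.0468, against 0.0279 and 0.305 with an estimated correlation. With 2 animals per sex and a biological coefficient of variation of 0.528 for genes, only large differences could pass.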

Results

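Polyadenylation sites were read in whole-body RNA of 2 adult female and 2 adult male Xenopus tropicalis, a diploid clawed frog. The question in the series title is how the use of alternative polyadenylation sites differs between the sexes. Each library is 1 frog. Totals were 2380500 and 1778737 reads in females 1 and 2 and 2779715 and 1531471 in males 1 and 2. A single site without a gene, on a scaffold, took 10.18% of the reads of female 2. Gene-level log2 CPM correlated across 10188 genes at 0.87 between the females and 0.86 between the males, and at 0.25 to 0.41 between the sexes (genes are not independent replicates).

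Transcripts of the egg were far higher in females, and transcripts of skeletal muscle and nerve were higher in males. The maternal POU factor gene pou5f3.3 (chromosome 8, most used site at 503680 on the minus strand) had 806 ± 215 CPM (SD, n = 2) in females and 0 reads in both males, at least 724-fold higher. velo1, whose product sits in the Balbiani body of frog oocytes, was at least 580-fold higher, and the cyclin genes ccna2 and ccnb1 at least 362-fold and 304-fold higher. hist1h2aa and patl2 were at least 280-fold and 243-fold higher, and all 6 genes had 0 reads in both males (edgeR, adjusted p from 0.00561 to 0.00577). Among abundant genes, ckm, the muscle creatine kinase gene (chromosome 8, most used site at 49713388 on the plus strand), had 2760 ± 2050 CPM in females and 49500 ± 30900 in males (SD, n = 2).

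The fitted log2 fold of ckm was 4.17 ± 1.33 (SE, adjusted p = 0.0413). The myosin light chain gene myl1 (3.84 ± 1.13, adjusted p = 0.0329), the glycolytic gene aldoa (3.22 ± 1.09, adjusted p = 0.0494), the skeletal actin gene acta1 (2.99 ± 0.91, adjusted p = 0.0357), the fast troponin gene tnni2 (3.80 ± 0.96, adjusted p = 0.0211) and the trypsin gene try10 (3.94 ± 1.07, adjusted p = 0.0261) were likewise higher in males. The calls of ckm, myl1, aldoa, acta1 and tnni2 ended without female 2. Abundant genes higher in females were rrm2.2, a ribonucleotide reductase subunit (log2 -9.32 ± 1.58), top1.2 (-5.23 ± 0.94), ier2 (-3.80 ± 1.03), the lamin gene lmnb1 (-3.53 ± 1.14), g3bp1 (-3.32 ± 0.95) and fam46c (-2.53 ± 0.75), with adjusted p from 0.00818 to 0.0437. With RLE size factors in place of TMM, aldoa (adjusted p = 0.0536) and lmnb1 (adjusted p = 0.0515) did not pass, nor did acta1 with library size alone (adjusted p = 0.053). Of genes with 0 reads in both females, an actb copy on chromosome 7 was at least 172-fold higher in males. Reads of actb copies cannot be assigned with certainty. spock2 (at least 70.1-fold), cacnb3 (57.5), fermt3 (53.7), ptprn2 (53.1) and nav1 (36.2) followed, and in spock2, cacnb3 and ptprn2 the most used site lay in an intron.

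In all, 1995 genes were higher in females and 1740 in males of 10188 tested, by edgeR's quasi-likelihood test. Of these, 449 had 0 reads in both males and 41 had 0 reads in both females. The sexes did not overlap in 7614 tested genes, where chance gives 33.3%. With library size alone in place of TMM, 24.1% of called genes were higher in males in place of 46.6%, and the median of all genes moved from -0.35 to -1.25. Scaled so that the somatic tissue lists (muscle, liver, nerve and the like) have a median of 0, 1.08% of called genes were higher in males and the median of all genes was -3.77, so that each fold change is relative to the TMM scale. The count was 1280 without female 1 and 1357 without female 2, where the lone female is assumed to vary like the males, and of 99 named genes 31 and 27 lost their call.

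Of genes reported whatever their result, zp2 and zp4, which encode egg coat proteins, had 93.4 ± 23.5 and 851 ± 272 CPM in females. zp2 was at least 83.9-fold higher there, and the zp4 ratio was 1160 (counting interval 321 to 9580) over 2 reads in the males. The oocyte growth factor bmp15 was at least 10.4-fold higher (adjusted p = 0.0178). cpeb1, which controls cytoplasmic polyadenylation in oocytes, was higher in females (log2 -5.90 ± 0.78, adjusted p = 0.00616), and so was the embryonic poly(A)-binding protein gene pabpc1l, at least 63.4-fold. pabpc1 was higher in males (2.44 ± 0.72, adjusted p = 0.0338), a call lost with library size alone (adjusted p = 0.0714) and a direction turned by the somatic scaling (log2 -0.99). nudt21, a cleavage factor subunit, had a log2 fold of -0.79 ± 0.83 (adjusted p = 0.473). gdf9 (21 reads in females, 0 in males), sycp1 (35 reads in males, 0 in females), sycp3 and cstf2 had too few reads for the test.

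The lists of egg and dividing-cell genes were higher in females. Of 36 tested oocyte and egg genes 35 were higher there, among them kpna7 (log2 -8.47 ± 0.81), velo1, pou5f3.3 and zpd (at least 151-fold), and 35 passed when adjusted over the list alone. The list's median log2 fold was -8.64, or -6.09 with genes at 0 reads set to their bound (adjusted p = 3.4e-15, and 0.18 with an estimated correlation). The estimated correlation of this list was -0.014, below the preset, so correlation between its genes did not raise that p. The smaller p treats genes as replicates, here and for the other lists. All 35 tested cell cycle genes were higher in females, with a median of -7.06, or -5.29 with bounds (adjusted p = 1.7e-13, and 0.21 with an estimated correlation), and 35 passed adjusted over the list alone. Examples are cdc20 (-7.34 ± 0.82) and ccnb1.2 (-7.78 ± 0.90). Of 17 tested lists camera called 12 with its preset correlation and 0 with an estimated one (3 at an unadjusted p under 0.05), and fry called 12. fry did not call the blood and gut lists, which camera called, and called the testis and meiosis lists, which camera did not.

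**Figure D1:**
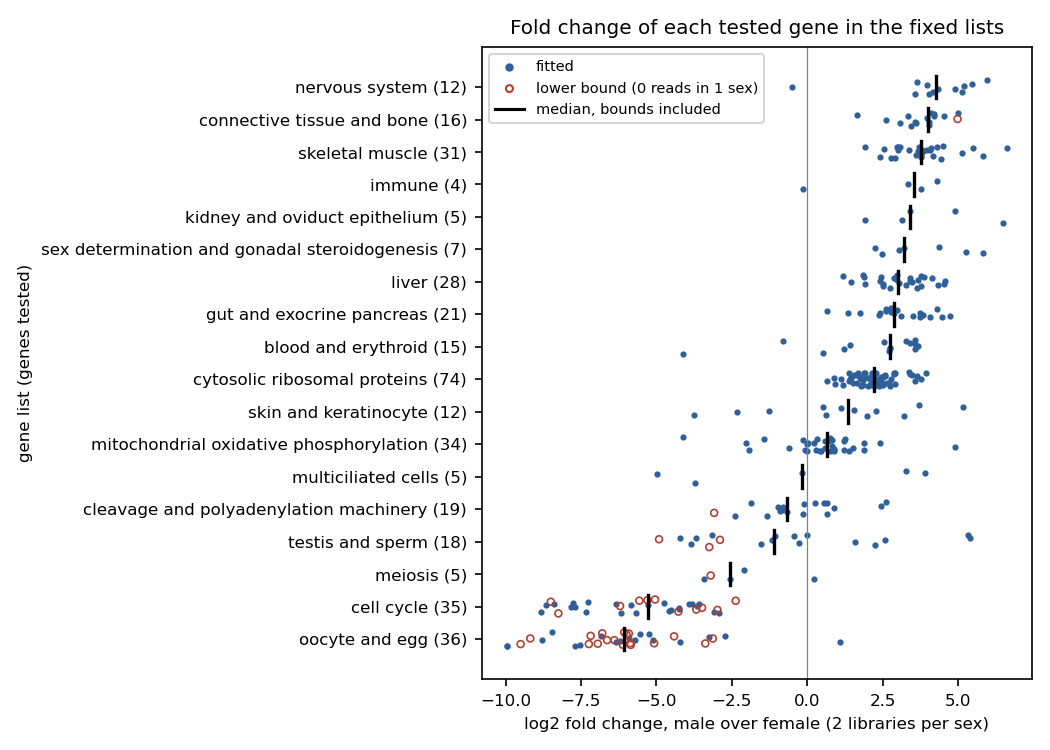
Log2 fold change (male over female, 2 libraries per sex) of each tested gene in the lists with at least 4 tested genes. Filled points are fitted values, open points are lower bounds of genes at 0 reads in 1 sex, and bars are medians with bounds. The oocyte and egg median lies at -6.09 and the nervous system median at 4.26.

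Most somatic tissue markers were higher in males, while 35 of the 36 tested egg markers were higher in females. On the somatic scaling each list median falls by about 3.43, which turns those of the liver, gut, blood, skin, kidney, sex determination, ribosomal and oxidative phosphorylation lists. Of 31 skeletal muscle genes 30 were higher in males (30 adjusted over the list alone; median 3.77, adjusted p = 1.6e-13, and 0.21 with an estimated correlation), including mybpc2 (6.62 ± 0.83), des.1 (4.43 ± 0.63), ryr1 (4.29 ± 0.62) and ldb3 (3.67 ± 0.59). The counts were 22 of 28 for liver (25 adjusted over the list alone; median 3.01, adjusted p = 1.1e-10, and 0.31 with an estimated correlation), with the kininogen gene kng1 at 4.52 ± 0.70 and the antithrombin gene serpinc1 at 4.14 ± 0.64. They were 13 of 16 for connective tissue and bone (15 adjusted over the list alone; median 3.99, adjusted p = 2.3e-07, and 0.21 with an estimated correlation), with the collagen gene col1a2 at 4.53 ± 0.86. For the nervous system they were 11 of 12 (11 adjusted over the list alone; median 4.25, adjusted p = 7e-06, and 0.21 with an estimated correlation), with gap43 at 5.96 ± 1.07 and the neurofilament gene nefh at 5.46 ± 0.92. For gut and exocrine pancreas they were 12 of 21 (17 adjusted over the list alone; median 2.89, adjusted p = 2.4e-06, with 0.31 for an estimated correlation and 0.093 for fry), with the peptide transporter gene slc15a1 at 4.73 ± 1.12.

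Blood and erythroid genes were higher in males for 8 of 15 and lower for 1 of 2 tfrc copies (9 and 1 adjusted over the list alone; median 2.75, adjusted p = 0.00097, with 0.40 for an estimated correlation and 0.095 for fry), with the globin gene hbg2 at 3.67 ± 0.90. The other tfrc copy had a log2 fold of -0.80 ± 0.74 (adjusted p = 0.409). For kidney and oviduct epithelium, 3 of 5 were higher in males (5 adjusted over the list alone; median 3.39, adjusted p = 0.0068, and 0.24 with an estimated correlation). Of 4 tested immune genes 3 were higher in males, among them cd74 (3.35 ± 0.63), and ptprc had a log2 fold of -0.15 ± 0.95. In the skin list ppl, krt19, evpl and dsp were higher in males, and krt18 (-3.77 ± 0.67) and cldn4 were higher in females (median 1.34, adjusted p = 0.06, and 0.31 with an estimated correlation; 5 and 2 adjusted over the list alone). vtga2, a vitellogenin gene expressed in the liver of laying females, was the tested member of its list and went the other way from the liver list, with 186 ± 13.3 CPM in females and 14.9 ± 11.7 in males (log2 -3.60 ± 0.71, adjusted p = 0.0115).

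Ribosomal protein genes were higher in males for 35 of 74 (45 adjusted over the list alone; median 2.21, adjusted p = 1.9e-14, and 0.27 with an estimated correlation), rpl31 by 3.92 ± 0.70. Of 7 tested genes of sex determination and gonadal steroidogenesis, gata4, ar, lhcgr, fshr and rspo1 were higher in males (7 adjusted over the list alone; median 3.21, adjusted p = 0.00047, and 0.21 with an estimated correlation). With library size alone fshr did not pass (adjusted p = 0.0887), and the somatic scaling turned it to -0.30. gata4 had a log2 fold of 4.38 ± 0.83. On the somatic scaling gata4 (log2 0.98), ar (2.71) and lhcgr (2.01) did not pass (edgeR, adjusted p = 0.364, 0.0929 and 0.17). The ratios of the androgen receptor gene ar and the luteinizing hormone receptor gene lhcgr were 79.3 (counting interval 13.5 to 3200) and 46.9 (12.3 to 397), and the most used site of each lay in an intron. Without intronic sites fewer than 5 genes of that list could be tested. Testis and sperm genes went both ways, with odf3 (5.39 ± 0.95) and tekt1 higher in males and brdt (-4.22 ± 0.62), tdrd5, tdrd9, adad2 and odf2 higher in females (3 and 6 adjusted over the list alone; median -1.12, adjusted p = 0.32, and 0.017 with fry). On the somatic scaling odf3 (log2 2.05) and tekt1 (2.23) did not pass (edgeR, adjusted p = 0.0932 and 0.144). Only 18 of the 35 testis and sperm genes had enough reads for the test, so that median leaves out the others. In the meiosis list meioc was higher in females (1 of 5, and 1 adjusted over the list alone; median -2.55, adjusted p = 0.15, and 0.017 with fry).

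In the cleavage and polyadenylation machinery, cpsf4 (at least 8.49-fold) and papolg (-2.41 ± 0.66) were higher in females and pabpc1 in males, with 16 of 19 not past the test and 0 adjusted over the list alone (median -0.66, adjusted p = 0.86). Oxidative phosphorylation genes had a median of 0.65 (adjusted p = 0.025, and 0.24 with an estimated correlation), which was -0.25 with library size alone. Of 34, cox6a2, the muscle form of a cytochrome oxidase subunit (4.91 ± 1.07), sdha and ndufa4 were higher in males and cox6c (-4.11 ± 0.91) in females (1 and 1 adjusted over the list alone). With library size alone sdha (adjusted p = 0.263) and ndufa4 (adjusted p = 0.125) did not pass, and the somatic scaling turned them to -1.55 and -1.01. Of 5 multiciliated cell genes wdr78 was higher in males and tubb4b (-4.97 ± 0.84) in females (2 and 2 adjusted over the list alone; median -0.17, adjusted p = 0.85). With library size alone wdr78 did not pass (adjusted p = 0.062), and the somatic scaling turned it to -0.10. The list median was 1.11 with no filter, 1.27 at 1 CPM in 2 libraries and -2.58 to 3.33 without 1 library.

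Single sites showed the same contrast between the sexes as genes did. Of 17215 tested sites, 3431 were higher in females and 2785 in males (edgeR). A stretch of chromosome 7 (plus strand, 9057033 to 9090084), singled out after its values were seen, had 116171 and 1809 reads in males 1 and 2 and 25 and 9 in females 1 and 2. Of its 23 sites 11 had no gene and the others lay in the loci LOC105947824 and LOC101731963. With library size alone 28.4% of called sites were higher in males in place of 44.8%. The count was 3146 without female 1, 2395 without female 2 and 13496 when sites of at least 1 CPM in 2 libraries were tested. In the authors' deposited table, FDR-adjusted p was under 0.05 at 4299 sites, of which 2962 were higher in females and 1337 in males. Of the sites called in the authors' deposited table, 3895 were tested here, 3809 were also called in the same direction, and 0 were called in opposite directions. Both tests used the same counts, from which the sign of the authors' fold was also judged, so the shared direction is no independent support. Of 6216 sites called here, 2407 were not called in the authors' deposited table.

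**Figure D2:**
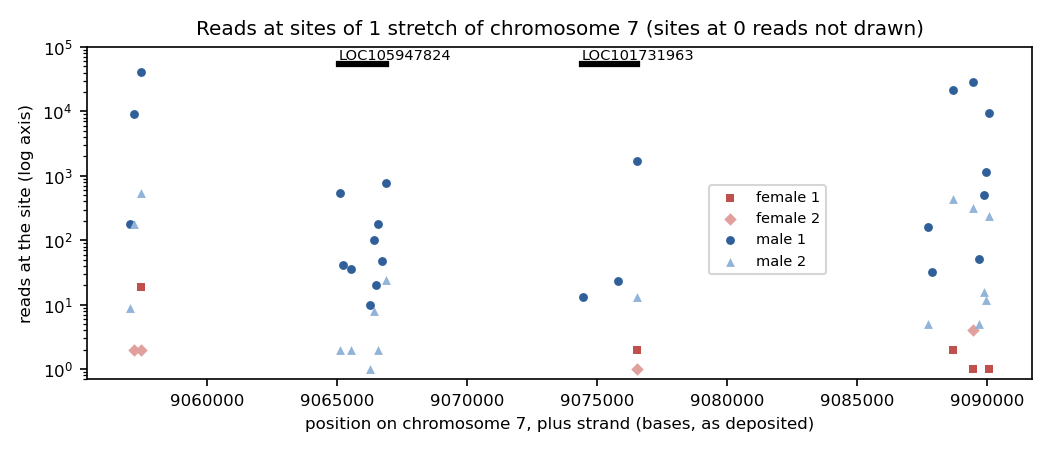
Reads (log axis, sites at 0 not drawn) at the 23 sites of a stretch of chromosome 7 against position in bases as deposited, with 1 marker per library and bars over the sites of each named locus. At 9057456 males 1 and 2 have 41315 and 540 reads and females 1 and 2 have 19 and 2.

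The use of sites differed between the sexes in genes such as h1fx, znrf1 and zfand6, and sites within introns took a larger share in males. In whole-body RNA, differing use within a tissue cannot be told apart from a differing mix of tissues, eggs included. In h1fx, a linker histone gene on chromosome 4, the middle of 3 sites (125132053, inside an exon) took 16.7 ± 1.6% of reads in females and 95.2 ± 1.0% in males (SD, n = 2). The last site (125132323, overlapping an exon) took 66.7 ± 14.2% and 3.7 ± 1.1%. In znrf1, a ubiquitin ligase gene on chromosome 4, the last site (26461417, minus strand) fell from 99.3 ± 0.0% in females to 50.3 ± 1.5% in males, and an intronic site (26472811) rose from 0.4 ± 0.0% to 19.5 ± 1.5%. Adjusted p of the gene-level test was 0.0034 for h1fx and 0.00124 for znrf1. In the test of single sites, the last site of h1fx (adjusted p = 0.0196) and the intronic site of znrf1 (adjusted p = 0.0168) passed. The middle site of h1fx (adjusted p = 0.115) and the last site of znrf1 (adjusted p = 0.72) did not.

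**Figure D3:**
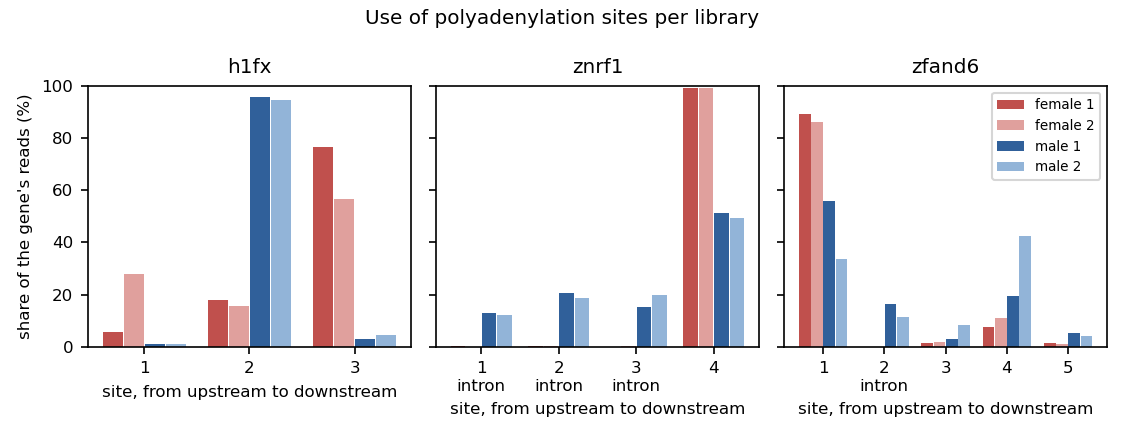
Share of the gene's reads (%) at each tested site of h1fx, znrf1 and zfand6, ordered from upstream to downstream, with 1 bar per library and intronic sites marked. The middle site of h1fx holds 95.9 and 94.5% of reads in the males and 17.8 and 15.5% in the females. It did not pass the test of single sites (edgeR, adjusted p = 0.115).

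The 2 most used sites of the 10 genes were chosen by a fixed rule, and 5 of these 20 passed the test of single sites. They were the last site of h1fx, the first site of actn3, and the intronic sites of znrf1, pak3 and arhgap21 whose shares are given. The most used site of zfand6, across an exon and an intron, took 87.8 ± 2.1% in females and 44.7 ± 15.5% in males, and an overlapping-exon site took 9.3 ± 2.4 and 30.9 ± 16%. Neither passed the site test (adjusted p = 0.748 and 0.286), and an intronic site with 0 reads in both females and 13.9 ± 3.7% in males did (adjusted p = 0.002). In pak3, a kinase gene, the last site took 56.8 ± 17.4% and 11 ± 9.6%, and an intronic site 2.3 ± 1.0% and 46 ± 9.4%. The change at the last site was -58.1 to 48.5 points without 1 library and turned to 41.8 without intronic sites. In arhgap21 the last site took 92 ± 4 and 63.3 ± 11.3%, and an intronic site 0.2 ± 0.2 and 20.1 ± 12.2%. That last site moved by -46.3 to 3.9 points without 1 library and turned to 3.2 without intronic sites. In kiaa0922 an intronic site took 21.7 ± 6.7 and 79.9 ± 3.8%, and an exonic site 42.9 ± 15.1 and 3.7 ± 0.5%. Neither of these kiaa0922 sites passed the site test (adjusted p = 0.243 and 0.0577). In actn3, the fast-fibre actinin gene, the last site took 79.9 ± 8.7 and 97.4 ± 0.9%, and the first 14.9 ± 9.9% in females with 0 reads in both males. The leading sites took 64.8 ± 27.9 and 22.3 ± 13.8% in pde4d, 58.3 ± 22 and 21.7 ± 15.7% in btrc, and 30.4 ± 2.0 and 46.3 ± 10.9% in zranb1. The second most used sites of these 3 genes took 13.3 ± 10.1 and 17.9 ± 1.4%, 10.8 ± 4.7 and 14.9 ± 4.9%, and 22.7 ± 7.3 and 20.3 ± 6.2%. None of these 6 sites passed the site test (adjusted p = 0.274 or more). Intronic sites that passed took 1.2 ± 1.3 and 9.5 ± 0.9% in pde4d (adjusted p = 0.0202) and 0.2 ± 0.2 and 17.8 ± 5.8% in btrc (adjusted p = 0.0133). In zranb1 one had 0 reads in both females and took 11.8 ± 1.2% in males (adjusted p = 0.0148). Sites outside introns also passed the site test with 0 reads in both males. In females they took 11.5 ± 0.4 and 10.1 ± 4.2% in zranb1 (adjusted p = 0.0153 and 0.0166) and 41 ± 18.4% in pak3 (0.0194). The last site of kiaa0922 took 32.7 ± 12.3% (0.013). In h1fx the first site took 16.7 ± 15.8 and 1.1 ± 0.1% (adjusted p = 0.0425). Further intronic sites passed in znrf1, pde4d, pak3, arhgap21 and btrc. Adjusted p of the 10 genes in the gene-level test was 0.00124 to 0.0034.

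In all, 551 of 3513 genes with at least 2 tested sites (15.7%) differed in site use by edgeR's diffSpliceDGE, 511 of them with a change of at least 10 percentage points, and 448 were not called at the gene level. Of 193 called intronic sites 186 were used more in males, against 11 of 90 called sites inside an exon, 1 of 30 overlapping an exon and 9 of 34 downstream. Shares within a gene sum to 100%, so a rise at an intronic site lowers the other sites by construction. Of all 1030 tested intronic sites, 785 had a log2 fold above that of the other sites of the gene. Whether intronic sites are true polyadenylation sites or come from priming on A-rich stretches was not tested. Without intronic sites 134 genes were called, and znrf1 could no longer be tested while kiaa0922 (adjusted p = 0.0983), pak3, arhgap21, btrc, pde4d and zfand6 did not pass. The count changed with the library left out: 230 genes passed without female 1, 2 without female 2 and 0 without male 1 (619 at an unadjusted p under 0.05), against 731 without male 2. Simes-adjusted site tests called 261 genes and limma 257.

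Where site use differed in whole-body RNA, males more often used upstream sites. Here too the mix of tissues cannot be told apart from use within a tissue. Of the called genes, 360 had a lower site index in both males than in both females, as in znrf1, pak3, btrc, arhgap21, zranb1 and h1fx, and 127 had a higher one, as in zfand6 and actn3. Upstream moves in males were thus 73.9% of those with a direction, while 63 genes overlapped, among them pde4d and kiaa0922, and 1 had a library without reads. Over 1949 genes with at least 20 reads in every library the mean index was 0.561 and 0.567 in the females and 0.488 and 0.521 in the males (exact permutation test, two-sided p = 0.333, the smallest that 2 against 2 can give). Intronic sites held 2.61 and 1.64% of reads at tested sites in females and 4.09 and 3.11% in males. Without intronic sites the share moving upstream in males was 56.8%. It was 64.3% without female 1, 50% of 2 genes without female 2 and 80.9% without male 2, and without male 1 no gene was called.

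Genes higher in males were more frequent on chromosome 7, which carries the sex-determining region of this frog. There 162 of 756 tested genes (21.4%) were higher in males, against 16.7% elsewhere (Fisher's exact test, two-sided, odds ratio 1.36, 95% interval 1.12 to 1.63, p = 0.00129). Adjusted over the 22 tests of 10 chromosomes and the scaffolds in both directions, p was 0.0284. Genes higher in females were 18.8% there and 19.6% elsewhere (Fisher's exact test, odds ratio 0.946, p = 0.6). mybpc2, ldb3, spock2 and rps19 are among the genes on chromosome 7 that were higher in males. Of these, mybpc2 and ldb3 belong to the muscle list and rps19 to the ribosomal list, both higher in males. Whether the excess follows the share of somatic tissue, or relates to the sex-determining region, was not tested. Genes are not independent replicates, and these p-values describe these 4 frogs.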

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

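Tests chosen after the data were seen are the scaling to somatic lists, the crossed block, the fits without intronic sites, the sums with opposite-strand sites, the same-strand sites and the lists without genes at 0 reads. Over all alternatives, 1374 values of named genes kept direction and side of the threshold, 147 lost the call, 31 gained one and 17 reversed. For lists the numbers were 186, 18, 8 and 7, and for named genes of site use 120, 29, 0 and 6. Without 1 library, differing sites numbered 2395 to 5777, genes 1280 to 4371 and genes of site use 0 to 731, and the upstream share was 50 to 80.9%, with no value without male 1. Counts fell or rose with the library left out, and the cause was not tested. The odds ratio of female-higher genes on chromosome 7 was 0.865 to 1.04, the multiciliated median -2.58 to 3.33, ptprc -1.04 to 1.66, the last site of pak3 -58.1 to 48.5 points and that of arhgap21 -46.3 to 3.9. At 1 CPM in 2 libraries, 13496 sites and 1361 genes of site use were called (more were tested) and the multiciliated median was 1.27, or 1.11 with no filter. With library size alone the oxidative phosphorylation median was -0.25. Site use gave 261 genes with Simes, 257 with limma, 73 with exonic sites and 134 without intronic sites, where the last site of pak3 moved by 41.8 and that of arhgap21 by 3.2 points in both fits, since the sites that rose were removed. The upstream share was 56.8% without intronic sites, 67.3% with the 2 most used sites and 68.3% over all genes with 20 reads. Without intronic sites ptprc and the multiciliated median were both at 0.11. With an estimated correlation, where camera also has the few degrees of freedom of these frogs, 0 lists passed. For these, unless the fewer or more features tested show it, the cause was not tested. Scaled so that somatic lists have a median of 0 (an offset of 3.43), 7577 genes were called, 1.08% of them higher in males, and aldoa (-0.20), acta1 (-0.44), pabpc1 (-0.99), fshr (-0.30), pabpc4 (-0.80), krt19 (-0.20), hbd (-0.71), alas2 (-0.02), cd74 (-0.06), lrp2 (-0.24), slc22a6 (-0.02), wdr78 (-0.10), sdha (-1.55) and ndufa4 (-1.01) reversed, as the offset makes genes of smaller fold do, sdha passing the test in the other direction. On that scaling 38 further named genes lost their call, and 6 gained a call or kept their direction with one. Merging sites within 25 bases joined 0 sites, and every called site and gene already had a log2 fold of at least 1.

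The replicate numbers do not pair the frogs in the labels, and the deviations of female 1 and male 1 correlated at 0.31 over genes. The replicate block gave 7469 sites, 4637 genes and 726 genes of site use and called 13 lists, turned ptprc to 0.27, and the crossed numbers gave 1486 genes. The immune list reached 5 tested genes in some alternatives and has no value in the test reported. Depth limits genes of few reads, such as gdf9, sycp1, sycp3 and cstf2.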

Other observations

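The tests of the chromosome 7 stretch, of the dilution of somatic RNA and of vtga2, and the values per pair of frogs and the t-tests between frogs, were chosen after the values they measure were seen, and the tests of intronic sites and of the chromosome 7 window before.

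A stretch of chromosome 7, plus strand, 9057033 to 9090084 as deposited, held 116171 reads in male 1 (4.18% of the library, Clopper-Pearson interval 4.16 to 4.20) and 1809 in male 2, against 25 and 9 in females 1 and 2. If reads of male 1 had been carried over into the library of male 2, male 2 would hold 1 share of the males' reads at each site. Among 14 sites with at least 100 male reads that share ran from 0.372% (0.0451 to 1.34) to 7.34% (3.22 to 14), which argues against carry-over as the whole source. The stretch took 0.118% of the reads of male 2 (0.113 to 0.124), against 0.00105% (0.00068 to 0.00155) and 0.000506% (0.000231 to 0.00096) in females 1 and 2. By counting error alone, male 2 thus lay above both females. The 95% prediction limit from 2 females, adopted after these values were seen, was 2.25% for 1 more frog. So wide a limit could hardly be exceeded, and it cannot decide whether male 1 alone carries the signal. A gene or genes expressed in males, a variant between frogs and reads shared with copies elsewhere in the genome stay open and untested.

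Somatic lists were lower in females, and egg RNA diluting all somatic RNA by 1 factor is a candidate explanation. Skin and keratinocyte (1.34; bootstrap interval -0.38 to 2.75, 0.87 to 1.92 over the 4 pairs of a male and a female) lay below the nervous system (4.25; 3.81 to 5.15, 3.98 to 4.82), but the skin list holds krt18 and cldn4, higher in females, which eggs could supply. Of the 21 comparisons among the 7 lists without a member higher in females, bootstrap intervals parted 3, such as gut and exocrine pancreas (2.61 to 3.73) and liver (2.63 to 3.56) from the nervous system, and the ranges over pairs parted liver alone (2.47 to 3.91; gut 1.96 to 4.21). In a t-test between frogs liver differed from the nervous system by -0.87 (95% interval -2.30 to 0.57), and 0 of the 21 intervals left out 0, against 3 of 36 with all lists, each with skin (nervous system -2.67, -3.71 to -1.64), so 1 factor stays open for the lists. vtga2 was higher in females (log2 -3.60), which dilution alone forbids for that gene, while dilution with further differences between tissues, and a difference of the sexes, stay open and untested.

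Intronic sites were used more in males, and 3 explanations were tested. Genomic DNA as a template would put about the same number of reads on both strands, but the opposite strand held at most 9.18% of intronic reads in a male library. If no filter on sites removed that strand, this argues against DNA as the whole source. A smaller part from DNA stays open. A rise with the amount of a gene's own RNA over the whole body is argued against as well. Over all 1030 tested intronic sites the log2 fold exceeded that of the gene's other sites by a median of 1.96 (1.73 to 2.17). It was 1.62 to 2.49 over the pairs of frogs, and the 95% interval of a t-test between frogs was 0.77 to 3.48. Whole-body RNA cannot exclude that intronic reads follow a gene's RNA within somatic tissue, if egg RNA adds to the other sites. Somatic tissue as the source may account for the pattern. The median log2 fold of all tested intronic sites, 3.98 (3.87 to 4.09), lay within the range of the somatic list medians, 1.34 to 4.25. That range is wide, with the skin list at its low end, so many features higher in males would lie within it. The count filter also keeps sites read in 1 sex alone, which can enlarge this median and that of 1.96 above. The 186 called sites alone had a median of 5.42 and the other sites of their genes -1.16, but they were chosen for a rise against those other sites and so decide nothing, and a difference of the sexes within a tissue and priming on A-rich stretches of RNA stay open.

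The excess of male-higher genes on chromosome 7 was tested for resting on 1 group of neighbours. Without the 10 Mb window that held the most such genes (25 of 91, from position 94961213), 20.6% of the tested chromosome 7 genes were higher in males. Fisher's exact p was then 0.012 with an odds ratio of 1.29 (1.05 to 1.57). That p was not adjusted over the 22 chromosome tests, and neighbouring genes are not independent. By the unadjusted p, that window alone does not carry the excess.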
